A study of Rattus norvegicus with 30 samples.

How the data were processed

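Gene expression was measured by bulk RNA sequencing of 30 samples: 5 healthy control nerves and 25 samples of tissue regenerated in a chitosan tube, taken 7, 14 or 21 days after immediate repair or after repair delayed by 3 months. Per the labels' protocols, libraries were made from 400 ng of total RNA with an integrity number above 6, by poly(T) capture of messenger RNA and without strand marking. Reads from a gene and from an overlapping or antisense gene therefore cannot be told apart. The deposited values are raw read counts per gene, whole numbers in 1 table of the series, and replicates were not pooled. The submitters' processing notes list HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.38.3 with no role or order. The genome build and the annotation release are not given in the sources used here. How reads shared between near-identical genes were counted is likewise not given, so single genes with such copies are uncertain.

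Each column was matched to its sample by the library name in the labels. Groups and replicate numbers came from the labels. The table lists 32545 Ensembl rat gene IDs, of which 8248 had 0 counts in every library. The table of gene symbols used here gives no Ensembl IDs, and 0 of the IDs matched it, so no symbol is printed and no gene is placed on the genome. Lists of cell type and pathway genes and the rule for named genes had been fixed by symbol before the data were examined. The lists were not tested. The rule took, in each comparison, the largest rises and falls among genes with adjusted p under 0.05, a mean log2 CPM of at least 1, a proper symbol and no overlap between the libraries of the groups compared. It also listed genes of the field to be named by symbol. It was applied without symbols, to the 2 largest rises of delayed against immediate repair at day 21 and the 2 largest falls of immediate repair against control at day 21. That reduction, and the choice of those comparisons, was made after the data had been seen.

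Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr given the groups, which left 16015 genes (49.2%), library sizes were scaled with TMM factors, and dispersions were estimated over all 30 libraries in 1 fit of 7 groups. The quasi-likelihood test with robust estimation gave p-values, adjusted by Benjamini-Hochberg over the genes tested in each comparison, with a threshold of 0.05. Because all groups share an estimate of spread, a group more dispersed than the rest is tested against too small a spread. A less dispersed group is tested against too large a spread. Comparisons were delayed against immediate repair at each day, each repair at each day against control, day 21 against day 7 in each repair, and the interaction of repair and day (an F test on 2 contrasts). Standard errors of log2 fold changes were taken from the test statistic, and 95% intervals from them. CPM values were computed with edgeR from the TMM-scaled library sizes. For correlations, principal components and distances, log2 CPM with a prior count of 2 was used. Correlations with control used the mean of the control libraries, leaving out the library itself where it was a control, and were compared with two-sided exact permutation tests, adjusted over 5 tests. The number of genes with counts at equal depth is the number expected if each library were drawn down to 11958242 counts, computed from its own counts.

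Replicates of a group were compared before use. The lowest chi-square per degree of freedom over the 51 pairs of replicates was 14.9, so no pair agreed within sampling noise. Genes were tested down to a minimum count of about 10 by the filter, so counting error adds to the spread between samples for genes of low count.

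The main test was run on simulated counts made from the real means, library sizes and gene-wise dispersions (tested on simulated data), with 100 genes changed 2-fold and 100 changed 4-fold. For delayed against immediate repair, on 15858 simulated genes at day 7, 34 of the 2-fold and 71 of the 4-fold changes were called, with 9 false calls. On 15848 genes at day 14, 35 and 71 were called with 4 false calls, and on 15877 genes at day 21, 37 and 69 with 4 false calls. No call had the wrong direction. Simulations that gave each group its own spread are taken up in the closing part.

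Alternatives fixed before the data were examined were DESeq2 1.42.0 with its own size factors on the same genes, relative log expression factors in edgeR, no filter beyond removing genes with 0 counts throughout (24297 genes), a fit of the compared groups alone, the replicate number as a block, and leaving out each library in turn. DESeq2 gave no adjusted p for 187 genes, which stayed without one. Added after seeing the data were limma 3.58.1 voom with sample quality weights, a fit without delayed day 7 replicate 5 and immediate day 21 replicate 4, a Pearson correlation with control, the fold of the day 7 rises in each library and with each library left out, the following of genes changed at day 7 in the other repair, and the comparisons of day 14 with its neighbouring days. The permutation tests of similarity to control were also chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.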

Results

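The series measured gene expression by poly(A) RNA sequencing in 30 samples of rat median nerve, a nerve of the forelimb. The nerve of adult females had been cut to leave a gap of 8 mm, which was bridged with a 10 mm tube of chitosan, a polysaccharide made from chitin. In the immediate repair the tube was placed at the time of injury, and in the delayed repair it was placed 3 months later. Tissue that had grown inside the tube was taken 7, 14 or 21 days after the repair. The groups held 4, 4 and 5 samples of immediate repair and 5, 4 and 3 samples of delayed repair at days 7, 14 and 21, beside 5 samples of healthy control nerve. Total counts per sample lay between 11958242 and 17334752, with a median of 14858868.5, and 16015 of the 32545 genes listed had enough counts to be tested. The labels number the replicates but do not say that each came from its own animal, so p-values here measure the spread between these samples. No batch is given. The files do not pair the Ensembl gene IDs with gene symbols, so the results are given for the libraries, the groups and sets of genes defined by their change, with 4 single genes named by ID.

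The first comparison asked how far the tissue in the tube differed from healthy nerve, and how far the samples differed from each other. Control libraries were nearly alike, with a Spearman correlation with the mean of the other control libraries of 0.990 ± 0.001 (SD, n = 5). At day 7 the correlation with the control mean was 0.697 ± 0.047 (SD, n = 4) after immediate repair and 0.726 ± 0.045 (SD, n = 5) after delayed repair. It was 0.820 ± 0.019 (n = 4) and 0.822 ± 0.018 (n = 4) at day 14, and 0.857 ± 0.046 (n = 5) and 0.844 ± 0.027 (n = 3) at day 21, for immediate and delayed repair in that order. Every day 21 library lay above every day 7 library of its own repair. The permutation tests that follow were chosen after the data had been seen. The rise from day 7 to day 21 was 0.160 after immediate repair (two-sided exact permutation test, p = 0.0159, Benjamini-Hochberg adjusted p = 0.0446 over 5 such tests) and 0.118 after delayed repair (exact permutation p = 0.0179, adjusted p = 0.0446). The delayed and immediate groups differed by 0.029 at day 7, 0.0022 at day 14 and -0.013 at day 21, none of which passed the exact permutation test (adjusted p = 0.648, 0.914 and 0.893). Leaving out any of the 8 delayed libraries at days 7 and 21 raised the adjusted p of the delayed rise to between 0.0714 and 0.143 (exact permutation test). Leaving out any of the 5 immediate libraries at day 21 raised that of the immediate rise to 0.0714. In none of these cases could the rise have passed, given the p-values of the other tests. Fewer arrangements of the samples then remain, which raises the smallest p that can be reached. That does not account for the 0.143 without delayed day 7 replicate 2, 3 or 4. Without replicate 1 or 5, at the same group sizes, the exact permutation test gave an adjusted p of 0.0714. Without the filter on low counts the rises were 0.0779 and 0.0565, with the same adjusted p in the exact permutation test.

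**Figure D1:**
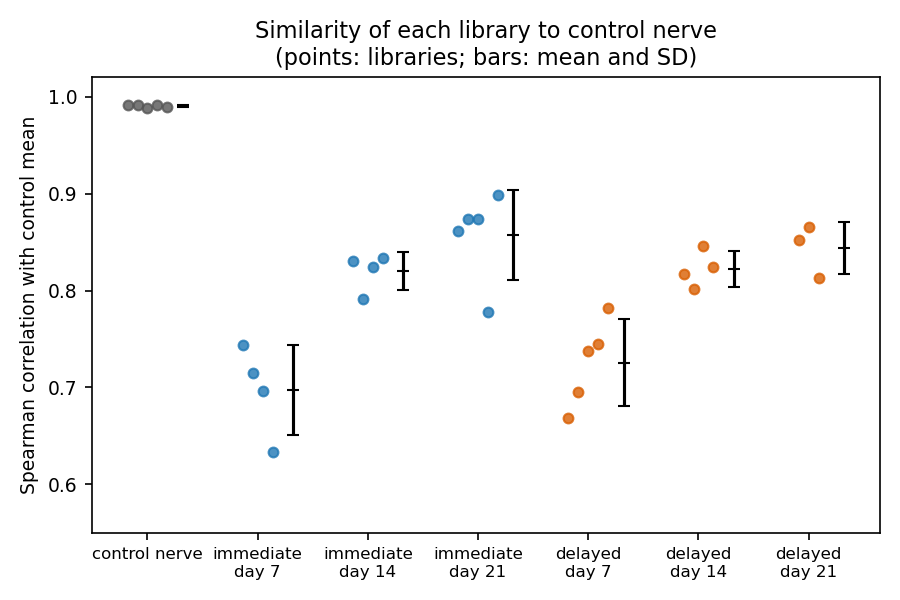
Spearman correlation of each library's log2 CPM with the mean of the control libraries (vertical axis, no unit) for the 7 groups (horizontal axis). Points are libraries and bars are the group mean and SD, and the values rise from 0.697 and 0.726 at day 7 to 0.857 and 0.844 at day 21 without reaching the 0.990 of control nerve.

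The leading principal component of log2 CPM held 52.5% of the variance and separated control nerve (-167.6 to -162.6) from day 7 tissue (29.6 to 188). Day 14 and day 21 tissue lay between -70.9 and 31.6, overlapping delayed day 7 replicate 5 at 29.6. The next component held 20.8% and set day 14 and day 21 tissue apart from both. Libraries of the immediate and the delayed repair were interleaved at each day. The day 7 groups were the most dispersed: the biological coefficient of variation estimated within a group was 52.9% at day 7 of immediate repair and 61.1% at day 7 of delayed repair, against 35.2% and 28.6% at day 14, 40.6% and 32.5% at day 21, and 20.5% in control nerve. At equal depth, 16692 ± 456 genes (SD, n = 4) had counts at day 7 of immediate repair and 17138 ± 271 (n = 5) at day 7 of delayed repair, against 17612 ± 129 (n = 5) in control nerve. The number was 17957 ± 161 and 17994 ± 143 at day 14 and 18174 ± 198 and 17892 ± 129 at day 21, in the same order.

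**Figure D2:**
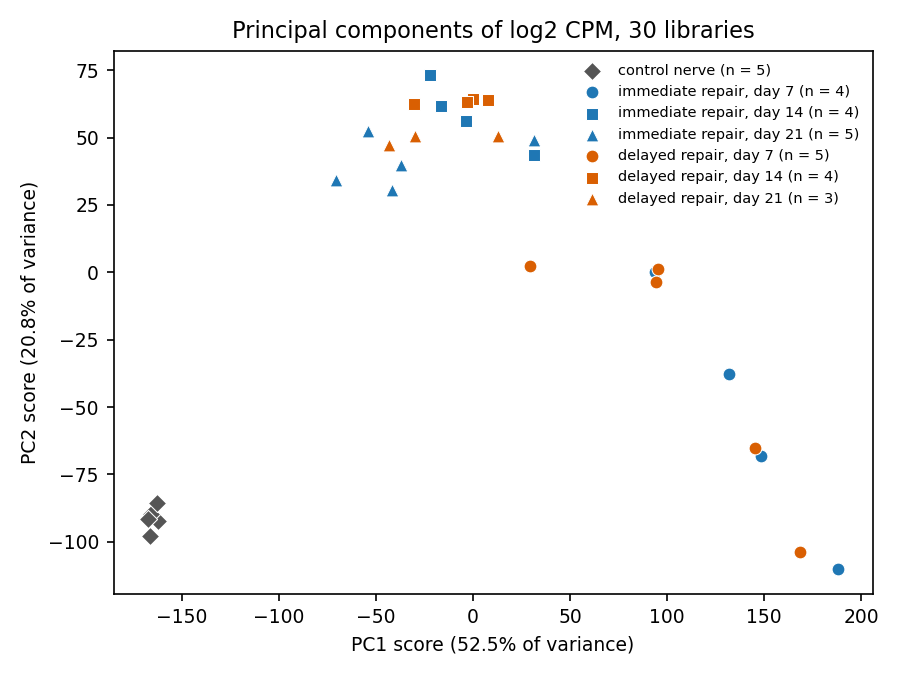
Scores of the 30 libraries on principal component 1 (horizontal axis, 52.5% of variance) and principal component 2 (vertical axis, 20.8% of variance), in score units. Color marks the repair and shape the day, and delayed and immediate libraries of the same day lie among each other while the 9 day 7 libraries are the most spread out, with delayed replicate 5 apart from the rest at 29.6 on component 1.

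Against control nerve, immediate repair changed most tested genes at day 7 and fewer with time. At day 7, 4829 genes rose and 5609 fell, together 10438 of the 16015 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 7180 differed at least 2-fold, and 4731 at least 4-fold, with more of the 4-fold changes being falls (2764) than rises (1967). At day 14, 4178 genes rose and 4061 fell, and 1726 rises against 1446 falls were 4-fold or more. At day 21, 3978 genes rose and 3658 fell, and the 4-fold changes comprised 1616 rises and 1042 falls. Thus 4-fold falls went from 2764 to 1042 between day 7 and day 21, while 4-fold rises went from 1967 to 1616. In 56.0% of all tested genes the 4 day 7 libraries did not overlap the 5 control libraries, where chance gives 1.59%. By the shortened rule for named genes, the 2 largest falls at day 21 were ENSRNOG00000003510 and ENSRNOG00000012460. ENSRNOG00000003510 measured 2.38 ± 1.47 CPM (SD, n = 5) after repair and 299.9 ± 106 CPM (n = 5) in control nerve, a log2 fold change of -6.97 (SE 1.10, edgeR adjusted p = 1.11e-05). ENSRNOG00000012460 measured 8.26 ± 3.39 CPM against 744 ± 62.4 CPM, a log2 fold change of -6.49 (SE 0.29, edgeR adjusted p = 2.40e-14).

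Against the same control libraries, delayed repair also changed 44.3% to 64.4% of the tested genes on each day. At day 7, 5044 genes rose and 5265 fell (10309 in all), with 2026 rises and 2316 falls of at least 4-fold. At day 14, 4197 rose and 4113 fell, with 1757 rises and 1410 falls of at least 4-fold. At day 21, 3697 rose and 3399 fell, with 1615 rises and 1188 falls of at least 4-fold. Counts of changed genes against control stayed within 1.5 times of these values in both repairs under each alternative tried and with any library of the groups compared left out. The order of days 7 and 14 of delayed repair turned in 2 of the alternatives: 8915 genes at day 7 and 9528 at day 14 when only the groups compared were fitted, and 10639 and 10791 with voom and sample quality weights.

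**Figure D3:**
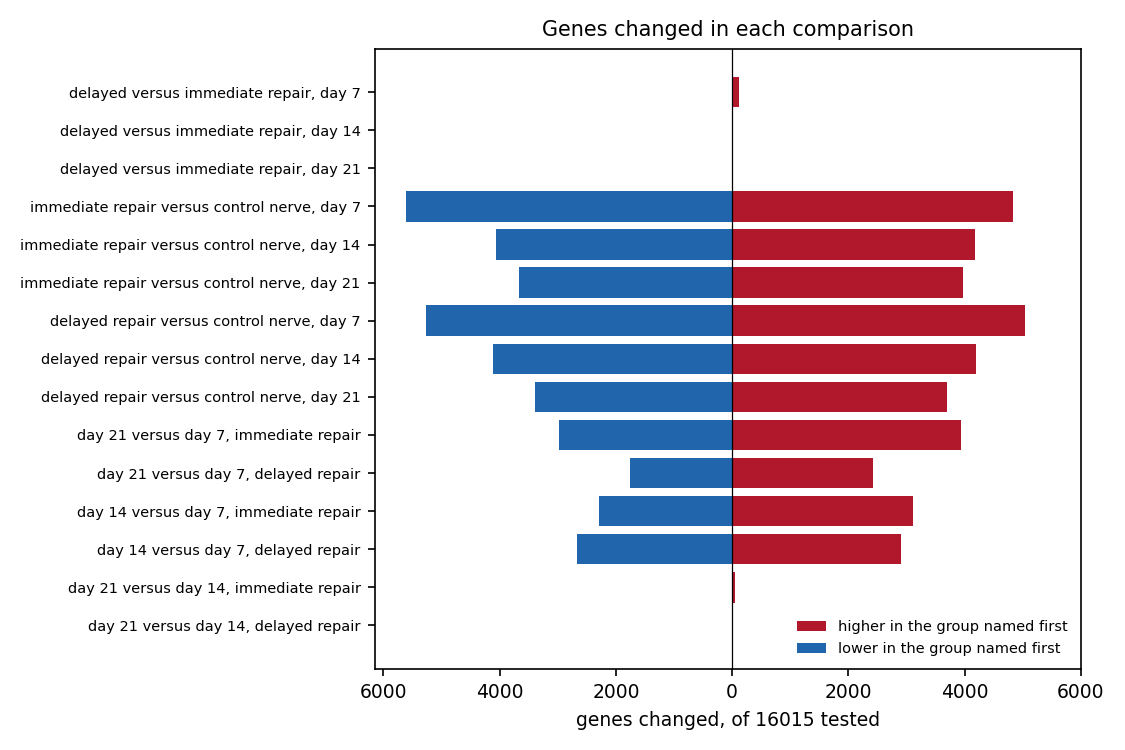
Genes higher (right) and lower (left) in the group named first, of 16015 tested (horizontal axis, number of genes; edgeR, adjusted p under 0.05), for each comparison (vertical axis). The bars against control nerve reach 10438 genes, whereas the bars for delayed against immediate repair hold 114, 0 and 8 genes.

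How alike the changes of the repairs were was measured without shared control libraries. The 5 controls were split into parts of 2 and 3, each repair was set against its own part, and the log2 changes were correlated across genes, which are not independent replicates. Over 20 such splits the median Pearson r between immediate and delayed repair was 0.966 at day 7, 0.955 at day 14 and 0.927 at day 21. Across days it was lower where day 7 was involved: 0.771 between immediate day 7 and delayed day 21, and 0.791 between immediate day 21 and delayed day 7, against 0.936 between immediate day 14 and delayed day 21.

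The next comparison asked how the tissue changed from day 7 to day 21. After immediate repair 3929 genes rose and 2973 fell (6902 in all), and most large changes were rises: 2048 rises and 429 falls were 4-fold or more. After delayed repair 2423 genes rose and 1756 fell (4179 in all), with 1217 rises and 337 falls of at least 4-fold. Whether the change over time differs between the repairs was tested as an interaction, given further on. The delayed count was 983 when the fit held only the delayed day 7 and day 21 libraries, and 2421 or 1934 without delayed day 21 replicate 1 or 2.

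Most of the genes that changed between days 7 and 21 moved back toward control nerve. To keep libraries apart, genes changed at day 7 in one repair were followed in the other. Of the genes changed at day 7 of delayed repair against control, 5525 also changed from day 7 to day 21 of immediate repair, and 5310 of these (96.1%) did so in the opposite direction. Independent lists of the same sizes would share 2228 genes with opposite and 2215 with the same direction. Of the genes changed at day 7 of immediate repair, 3397 also changed from day 7 to day 21 of delayed repair, 3228 of them in the opposite direction, against 1378 for independent lists. Without delayed day 21 replicate 1 or 2 the number of opposite changes in the reciprocal set was 1959 or 1587.

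Genes that stood far from control nerve at day 7 in either direction stood nearer to it at days 14 and 21. Genes at least 4-fold higher or lower at day 7 of one repair than in 3 of the control libraries, with no overlap between libraries, were followed in the other repair against the remaining 2 control libraries. Only genes with a mean log2 CPM of at least 1 over all 30 libraries were taken. That mean includes the libraries measured, so the choice was not independent of them. It can favor lower genes that recovered and higher genes that stayed high, and its effect was not tested. The genes chosen as lower in delayed repair (1406 to 1429 genes over the 10 ways to choose the controls) stood at a median log2 change of -4.04 ± 0.94 (SD of library medians, n = 4) at day 7 of immediate repair. They stood at -1.73 ± 0.33 (n = 4) at day 14 and -1.36 ± 0.42 (n = 5) at day 21. The genes chosen as higher (1185 to 1226) stood at 3.57 ± 0.11 at day 7, 2.79 ± 0.39 at day 14 and 2.48 ± 0.38 at day 21. At day 21, 87.9% of the higher genes and 63.7% of the lower genes were still at least 2-fold away from control in the same direction. The reciprocal sets did likewise: genes lower at day 7 of immediate repair went from -3.27 ± 1.05 (n = 5) at day 7 of delayed repair to -1.45 ± 0.17 (n = 4) at day 14 and -1.36 ± 0.35 (n = 3) at day 21. Genes higher at day 7 went from 3.35 ± 0.24 through 2.66 ± 0.30 to 2.61 ± 0.24. At day 21, 91.0% of the higher and 61.0% of the lower genes were still 2-fold away. No test was made of the difference between the higher and the lower genes.

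**Figure D4:**
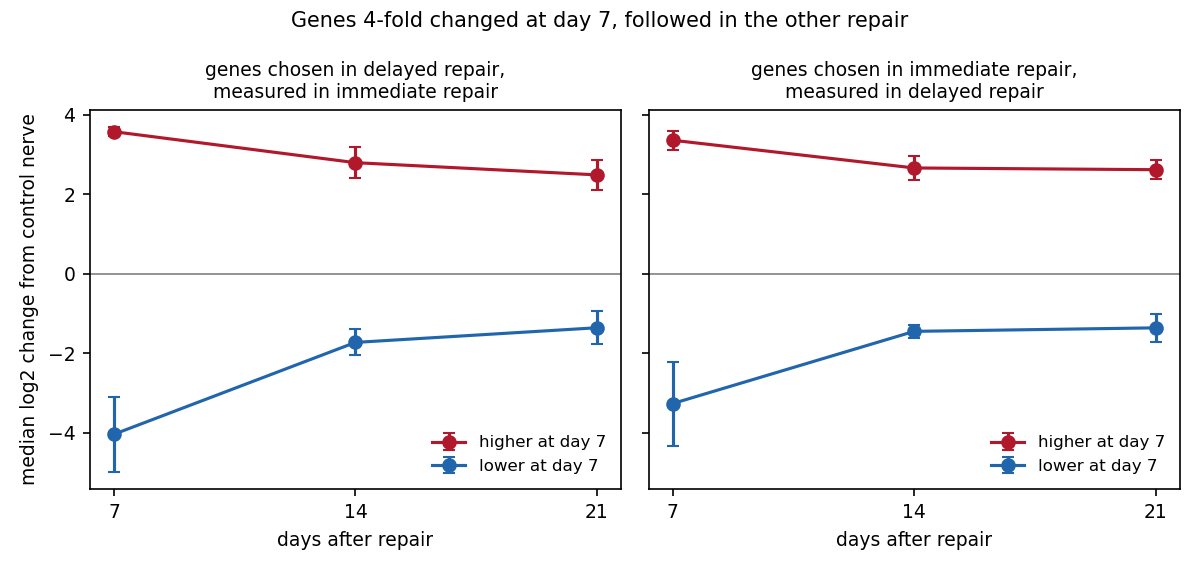
Median log2 change from control nerve (vertical axis) at 7, 14 and 21 days after repair (horizontal axis) of genes at least 4-fold higher or lower at day 7 in the other repair. Points are means of library medians and bars their SD (n = 3 to 5), and the lower genes move from -4.04 to -1.36 while the higher genes move from 3.57 to 2.48 in the left panel.

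Delayed and immediate repair were then compared at each day. This is the question the design puts: whether regenerating tissue differs after a wait of 3 months before the repair. Delayed samples were also taken longer after the injury, and the same control nerves serve both repairs. The wait cannot be told apart from what came with it. At day 7, 111 genes were higher and 3 lower after delayed repair (edgeR, adjusted p under 0.05, 5 against 4 libraries), 113 of them at least 4-fold. The 111 rises lay close to the threshold, with a median edgeR adjusted p of 0.0491 and a median log2 fold change of 6.08 (median SE 1.36). Of them, 102 had their highest value in delayed day 7 replicate 5 and the other 9 in replicate 4. The groups did not overlap in 8 of the 114 genes, and over all tested genes in 0.375%, where chance gives 1.59%. Against the mean of the immediate libraries, the median log2 CPM difference of the 111 rises was 6.87 in delayed replicate 5, 2.52 in replicate 4 and 1.93 in replicate 3, but 0.20 in replicate 2 and 0.09 in replicate 1. Leaving out replicate 5 left 1 call and took the median log2 fold change to 2.43 (median SE 0.86). Leaving out delayed replicates 1, 2, 3 or 4 gave 360, 320, 232 or 189 calls. Leaving out immediate replicates 1, 2, 3 or 4 gave 0, 3, 0 or 0 calls, with median log2 fold changes of the rises of 6.71, 6.03, 6.20 and 5.98. Leaving out any of the 21 libraries outside the comparison, control libraries included, left 6 to 17 calls at a median log2 fold change of 6.07 to 6.08. The count was 341 with DESeq2, 0 with voom and sample quality weights, 15 with relative log expression factors, 7 without the filter and 0 when only the 9 day 7 libraries were fitted. Over all tested genes, 1352 had an unadjusted p under 0.05. The 95% interval of the log2 difference had a median half-width of 0.57 and lay within a 2-fold change in either direction for 58.9% of genes.

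In delayed day 7 replicate 5, 98 genes above 5 CPM measured more than 10 times their value in every other library and took 9.34% of its counts. Their median was 170 CPM in that library, while the median of their highest values in the 5 control libraries was 1.89 CPM. Of the 98, 35 were among the genes called higher at day 7.

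**Figure D5:**
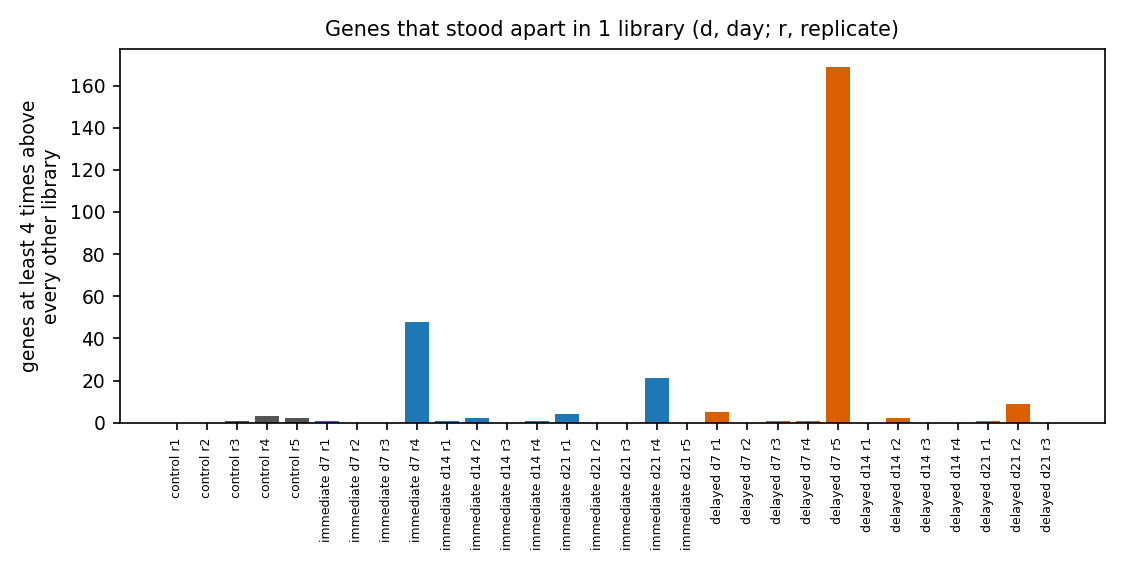
Number of genes above 5 CPM and at least 4 times above every other library (vertical axis, genes) in each of the 30 libraries (horizontal axis; gray control, blue immediate, orange delayed repair). Delayed day 7 replicate 5 held 169 such genes and immediate day 7 replicate 4 held 48.

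At day 14 no gene differed between delayed and immediate repair by the edgeR test (4 against 4 libraries). An unadjusted edgeR p under 0.05 was reached by 244 genes, 1.52% of those tested, where 5% is expected without any difference. A shared spread too large for these groups may contribute, but the source of this shortfall was not tested. With the day 14 libraries fitted alone, 371 of 14307 genes had an unadjusted edgeR p under 0.05, and none was called. DESeq2 called 7 genes and limma voom with sample quality weights 2. The groups did not overlap in 1.90% of tested genes, where chance gives 2.86%. The 95% interval lay within a 2-fold change for 59.7% of genes in the main fit and 74.6% in the fit of the day 14 libraries alone. Smaller differences, and larger ones in the remaining genes, are therefore not excluded.

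At day 21, 8 genes were higher and none lower after delayed repair by the edgeR test (3 against 5 libraries), and in all 8 the groups did not overlap. Over all tested genes the groups did not overlap in 4.21%, where chance gives 3.57%, and 911 genes had an unadjusted p under 0.05. ENSRNOG00000008015 measured 891 ± 656 CPM (SD, n = 3) after delayed and 40.9 ± 12.1 CPM (n = 5) after immediate repair, against 136 ± 120 CPM (n = 5) in control nerve. Its log2 fold change between the repairs was 4.45 (SE 0.82, edgeR adjusted p = 0.0364). ENSRNOG00000043465 measured 65.3 ± 45.9 CPM after delayed and 3.35 ± 2.96 CPM after immediate repair, against 6.26 ± 1.66 CPM in control nerve, a log2 fold change of 4.27 (SE 0.77, edgeR adjusted p = 0.0364). Without the filter on low counts no gene was called, and the adjusted p of both genes was 0.0741 (edgeR). Without delayed day 21 replicate 1 or immediate day 21 replicate 1, 3 or 5 no gene was called at day 21. Without delayed replicate 2, 1 was called, which was not among the 8, and without immediate replicate 2, 3 were called, 2 of them among the 8. ENSRNOG00000008015 kept its call without delayed replicate 3 alone of the 8 libraries compared, and ENSRNOG00000043465 without delayed replicate 3 or immediate replicate 2, at log2 fold changes of 3.74 (without delayed replicate 2) to 4.87 and 3.87 (without delayed replicate 2) to 4.98. Of the libraries outside the comparison, leaving out control replicate 4, delayed day 14 replicate 4 or immediate day 14 replicate 2 left none, control replicates 1 or 2 left 3 or 1, and immediate day 7 replicate 4 or delayed day 7 replicate 1 gave 19 or 13. Without immediate replicate 4, 7 genes were called, 3 higher and 4 lower, of which 2 were among the 8. DESeq2 called 57 genes, 42 higher and 15 lower, and voom with sample quality weights 54, 48 higher and 6 lower, and each included the 8. The fit of the 8 day 21 libraries alone called 1.

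Whether the difference between the repairs changed with the day was tested as an interaction. No gene passed the edgeR test (smallest adjusted p = 0.142), while 951 had an unadjusted p under 0.05. DESeq2's likelihood ratio test called 115 and voom none. Without delayed day 7 replicate 1 or 2 the edgeR count was 25 or 23. No gene was changed in the same direction on all 3 days by edgeR, DESeq2 or voom. For edgeR, with no call at day 14, and voom, with none at day 7, this held by necessity. DESeq2 called 341, 7 and 57 genes at days 7, 14 and 21. At an unadjusted edgeR p under 0.05 on each day there was 1 such gene, where independent lists would share 0.26.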

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

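The tests of the day 7 rises in this part were chosen after the result was seen. In groups of 4 or 5 samples, a library was picked out when its gap to the nearest other library was large against the range of its group by Dixon's criterion, over 24 combinations of group and measure. For normally distributed values chance picks out about 1 in 20, and 5 were picked out. The total count of delayed day 14 replicate 2 was 12628256, below the other 3 libraries of its group. The number of genes above 5 CPM and at least 4 times above every other library was 169 in delayed day 7 replicate 5, 48 in immediate day 7 replicate 4, 21 in immediate day 21 replicate 4 and 2 in delayed day 14 replicate 2. This number is often tied within a group, so the rate of 1 in 20 does not hold for it, and the 5 are not shown to exceed chance.

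The 111 rises called between the repairs at day 7 were uneven over the delayed libraries. An effect of delayed repair on these genes in each sample is argued against: their median log2 difference from the immediate mean was 0.09 in replicate 1 and 0.20 in replicate 2 (upper quartiles 0.77 and 0.91), against 1.93, 2.52 and 6.87 in replicates 3, 4 and 5. A piece of other tissue or other cells in replicate 5 stays open as a candidate explanation of the rises, in part or in full. Without that library they lay at a median log2 difference of 1.30 (quartiles 0.60 and 1.83). Their edgeR log2 fold change had a median of 2.43 (SE 0.86), against 6.08 (SE 1.36) with it. The genes were chosen as rises with the same other libraries, so the remaining difference is inflated by that choice. It cannot show how much of the rises replicate 5 accounts for. Without that library the call count fell to 1 with the lower fold, whereas without an immediate library it fell to between 0 and 3 with the fold at 5.98 to 6.71 and larger SE of 1.54 to 1.70, and without any library outside the comparison to between 6 and 17 with the fold kept. The median edgeR adjusted p of the rises was 0.0491 with all libraries. Without a library outside the comparison it was 0.0551 to 0.0633, with the median SE at 1.36 to 1.39. Those counts thus fell as rises near the threshold moved just past it. Why the adjusted p moved, and why the counts fell without delayed replicate 5 or an immediate library, was not tested. The wider spread at day 7 than the shared estimate remains open too: counts simulated with the spread of each group gave 123 false calls at day 7 (60 higher and 63 lower), against 9 with the shared spread, though the real calls were 111 higher and 3 lower.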

How the results depend on the processing

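The similarity tests, the voom weights and the fit without the doubted libraries were chosen after seeing the data. Counts against control and for day 21 against day 7 of immediate repair stayed within 1.5 times under every alternative, but the fall from day 7 to day 14 of delayed repair became a rise with only the groups compared (8915 to 9528) and with voom weights (10639 to 10791). Delayed against immediate repair did not. At day 7 the 114 genes became 15 with relative log expression factors, 7 without the filter, 0 with only the groups compared, 341 with DESeq2, 0 with voom weights and 1 without delayed day 7 replicate 5 and immediate day 21 replicate 4; leaving out 1 library of these groups gave 0 to 360, and 1 of any other group 6 to 17. At day 21 the 8 became 0 without the filter, 1 with only the groups compared, 57 with DESeq2 and 54 with voom weights, and 0 to 9 with 1 library of these groups left out and 0 to 19 with 1 of any other. At day 14 the 0 became 7 with DESeq2 and 2 with voom weights. The interaction went from 0 to 115 with DESeq2 and to 0 to 25 with 1 library left out. Day 21 against day 7 of delayed repair went from 4179 to 983 with only the groups compared and 1934 to 5420 with 1 library left out. The cause was not tested, except that the unfiltered fit tested 24297 genes and left-out fits held fewer samples.

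With the replicate block the counts were 0 at days 7 and 21, and the named rises of day 21 lost their call (log2 changes of 3.99 and 4.25). Of the counts added later, the 41 genes of day 21 against day 14 of immediate repair became 0. No other count moved by over 1.5 times. Whether the numbers pair the samples was not settled. Of 58 same-numbered pairs, 13 deviated together with a correlation over 0.1 (range -0.66 to 0.41), and 8 of 30 libraries correlated best with their own number. What chance gives was not computed. Between delayed and immediate repair the correlations were -0.66 to -0.11 at day 7, 0.08 to 0.41 at day 14 and -0.07 to -0.02 at day 21.

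With 1 library left out, the rise in similarity to control from day 7 to day 21 was 0.139 to 0.181 after immediate and 0.103 to 0.132 after delayed repair. It was past the threshold in 4 of the 9 immediate and 0 of the 8 delayed cases. Given the other tests, only leaving out an immediate day 7 library left enough arrangements of the samples to pass. The group sizes therefore set this split, and it does not rank the repairs. The difference between repairs, never past the threshold, was 0.0074 (without immediate replicate 4) to 0.044 (without immediate replicate 1) at day 7, -0.0073 to 0.0091 at day 14, reversed without immediate replicate 2 (-0.0073) or delayed replicate 3 (-0.0056), and -0.034 to 0.0024 at day 21, reversed without delayed replicate 3 (0.0024). The 2 named rises at day 21 lost their call without the filter and with only the groups compared, and ENSRNOG00000043465 without the doubted libraries (edgeR adjusted p 0.0518). With 1 library of the groups compared left out, both lost it without delayed day 21 replicate 1 or 2 or immediate day 21 replicate 1, 3, 4 or 5, and ENSRNOG00000008015 also without immediate replicate 2, at log2 changes of 3.74 to 4.98 over these 8 libraries. Of the other libraries, leaving out control replicate 4, delayed day 14 replicate 4 or immediate day 14 replicate 2 left no call at day 21 either, and the named rises were not followed singly there. The gene list alternatives were not run. Depth limits the genes of low count, which were tested from a filter minimum of 10 and, for ENSRNOG00000003510, with as few as 6 counts in a library. More depth would not lower the variation between samples, 20.5% in control nerve and 28.6% to 61.1% after repair.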

Other observations

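The tests in this part on the day 7 spread, and the comparisons of day 14 with its neighbouring days, were chosen after seeing the data. Most of the change over time lay between day 7 and day 14. From day 7 to day 14, 3119 genes rose and 2285 fell after immediate repair and 2896 rose and 2661 fell after delayed repair (edgeR, adjusted p under 0.05). From day 14 to day 21, 41 genes rose and none fell after immediate repair, and none changed after delayed repair, where 620 genes had an unadjusted p under 0.05 and DESeq2 called 36 and voom 69. With delayed day 7 replicate 5 and immediate day 21 replicate 4 left out, 294 and 43 genes changed from day 14 to day 21. After immediate repair DESeq2 called 153 and voom 170, and leaving out day 21 replicate 4 gave 185, day 21 replicates 1, 3 or 5 gave 21, 21 or 12, day 14 replicate 4 gave 15 and day 14 replicates 1, 2 or 3 gave 0. After delayed repair, leaving out day 21 replicate 3 gave 22 and replicate 2 gave 1. Without the filter the 41 became 26. Fitting only the groups compared gave 0 and 1 for the later interval and 3021 and 3347 for the earlier. After delayed repair the later interval compared 3 with 4 libraries, fewer than the 4 with 5 of the earlier. After immediate repair it compared 5 with 4, more than the 4 with 4 of the earlier.

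The 9 day 7 libraries did not gather around 1 profile. A hypothesis is that they stood at different points of the change that both repairs pass through between day 7 and day 14. On a scale where 0 is the day 7 mean and 1 the day 14 mean of the other repair, delayed day 7 replicates 1 to 5 stood at -0.22, -0.03, 0.38, 0.38 and 0.66, and immediate day 7 replicates 1 to 4 at 0.23, -0.09, -0.28 and -0.55. This direction held 32.1% of the spread within delayed day 7 and 22.4% within immediate day 7, against 3.46% and 12.98% at day 14, 8.36% and 8.90% at day 21 and 0.189% in control nerve. With 1 library left out the shares went from 12.1% to 26.4% at immediate and 23.5% to 35.3% at delayed day 7. They went from 3.90% to 19.1% at immediate and 0.472% to 4.55% at delayed day 14, and 4.18% to 11.1% and 0.676% to 13.01% at day 21. The ranges of immediate day 7 and the later groups overlap, so the hypothesis stays open. Unequal depth of counting by itself is argued against, since the share in delayed day 7 was 31.6% after thinning all libraries to the same total. Still, the highest positions in delayed and immediate day 7 belonged to the libraries with the highest totals of their groups, 17334752 and 16058103. The lowest positions belonged to those with the lowest totals, 12176007 and 11958242. Thinning does not remove other differences between samples that go with the total. Whether the samples may differ in the tissue taken or in the pace of regeneration was not tested.

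Other splits of the same libraries show how much this spread matters between the repairs. At day 7, 59 of 100 splits of the 9 libraries into 5 and 4 gave at least the 114 genes of the real split. The highest gave 3977 and put delayed replicates 1 and 2 with immediate replicates 2, 3 and 4, many times the real count, which points to a structure among these samples that does not follow the repair. At day 14 the real count of 0 is reached by all 35 splits whatever they hold, and the highest other was 0. At day 21, 4 of 56 splits gave at least 8 genes, with 45 as the highest of the others, so chance is not excluded. For the interaction, regrouping the repairs within each day gave up to 3343 genes against the real 0, which all 100 of the splits reach by necessity. The same holds for the count on all 3 days, 0 in each of the 100. For real counts of 0 the splits therefore test nothing, though 3343 points to a structure among the samples.

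Against control, chance is unlikely: in each of the 6 comparisons 1 of the splits, the real one, gave as many genes, of 100 drawn or, for delayed day 21, of 56. The 6 comparisons share the same control libraries, so they are not independent of each other. The real counts of 10438, 8239 and 7636 after immediate repair stood against highest other counts of 6966, 5332 and 1591, and those of 10309, 8310 and 7096 after delayed repair against 4714, 5573 and 1537. For day 21 against day 7 of immediate repair, 1 of 100 splits reached 6902, with 5874 as the highest other. For delayed repair 3 of 56 splits reached 4179, with 4755 as the highest other from a split that set delayed day 7 replicates 1, 2 and 4 apart, so chance is not excluded by this count. For day 14 against day 7 the real split was alone among 35 after immediate repair (5404 genes, highest other 2640) and 2 of 100 reached the 5557 genes of delayed repair (highest other 6127, with delayed day 7 replicates 1 to 4 set apart). For day 21 against day 14, 6 of 100 splits reached 41 genes after immediate repair (highest other 318), and all 35 reached, by necessity, the 0 of delayed repair (highest other 1).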
